A study of Homo sapiens with 18 samples.

How the data were processed

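RNA of epithelial cells, stem cells and stromal cells from the prostate of human donors was measured on 18 microRNA arrays, 17 of which belong to 6 donors by their labels (miRCURY LNA microRNA Array, version 9.2, with probe names from miRBase 11.0). The RNA was labelled with Hy3 per the labels, and the labels do not state how the cells were separated or whether they were cultured. Each slide was scanned on a GenePix 4000B scanner at 532 nm and 635 nm, and the spots were measured with GenePix Pro 6.1.0.4 without normalisation per the file headers. The deposited scanner files give, per the file headers, the median foreground and the local background of each spot as fluorescence intensity, and the percent of its pixels at the scanner limit. A deposited table of values for the series holds 685 probes on a linear intensity scale. Checked against the scanner files, its values follow the background-subtracted 532 nm intensity averaged over the 4 spots of a probe, but with a scaling that is not stated and that differs between arrays, with some values below 0. It was therefore used only as an alternative.

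The 532 nm channel, which holds Hy3, was analysed. The 635 nm channel held signal on few of the 9792 spots of an array, at most 229, and was left out. The comparisons, the rule for named microRNAs, the lists and most alternatives were fixed before the data were examined. Background was corrected with the normexp method of limma 3.58.1 in R 4.3.3 with an offset of 50, values were put on the log2 scale and quantile normalised over all microRNA spots of the 17 compared arrays, and the 4 spots of a probe were averaged. Probes with a human name were kept (569) if the foreground exceeded the local background by 2 background SD on at least 5 arrays, which left 557. This filter was weak, because the 7 negative control probes often passed it too. A negative control limit, the median plus 3 median absolute deviations of the negative control spots of an array, was therefore added after seeing the data, and 195 human probes exceeded it on at least 5 arrays. Where no array of the dimmer group exceeded this limit, or its mean lay under it, a fold is given as a lower bound, and no fold is given where that holds for both groups. Log2 differences are those of the fit, and they are not read as sizes where the dimmer group lay under the limit. The bound sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest normalised value above the limit on that array and the value of the probe itself. The files name no genome build, so no positions are given.

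Group means of the 17 arrays were fitted with limma, tests were moderated with eBayes, and a probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all probes tested in a comparison. All limma tests are two-sided. The comparisons were stromal against epithelial, stem against epithelial and stem against stromal arrays. Named microRNAs are, in each comparison, the 10 called probes with the largest log2 difference in each direction among those with the same sign in every donor that has both cell types, up to 4 tested members of each list with the largest absolute difference, and miR-205, miR-200c, miR-143, miR-145, miR-221, miR-222, miR-21 and let-7a. The same rule was applied without the stem array of donor A. Its first part required the same sign in every donor, so donor counts given with probes it named are not read as support. The 16 lists hold epithelial, fibroblast and mesenchymal, muscle, pluripotency, blood cell, endothelial and nerve cell microRNAs, the imprinted cluster at 14q32, the miR-17-92 cluster with its paralogs, the let-7 family, miR-15 and miR-16 with the X-linked cluster of miR-424, the miR-34 family, the miR-29 and miR-30 families, the clusters of miR-23, miR-27 and miR-24, the family of miR-99, miR-100 and miR-125, and miR-221 with miR-222. Lists with at least 3 tested members were tested with camera of limma at a preset correlation between probes of 0.01 and again with an estimated correlation, and p-values were adjusted over the lists of a comparison. The fry test of limma was planned beside camera. For all 17 arrays its adjusted p is given where it disagreed with camera at the preset correlation on passing the threshold. Measures of whole arrays were compared with exact two-sided permutation tests, adjusted over the 3 comparisons.

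Donor letters pair the arrays by design, since the labels give the same number to cells of the same donor. In a check of this pairing, deviations from the group means correlated above 0.1 in 7 of 16 pairs of arrays of the same donor (median 0.0871, from -0.0796 to 0.381). The fit with the donor as a block was run as an alternative. Batches were read from the scan information in the file headers. The procedure was tested on simulated data in which 50 probes were changed at each of several sizes. At a log2 change of 1 it recovered 100% of the changed probes for stromal against epithelial, 82% for stem against epithelial and 98% for stem against stromal arrays. In the same order, 9.43%, 5.67% and 4.02% of the calls were unchanged probes. The shares of 9.43% and 5.67% lay above the threshold of 0.05 for calls. These rates describe the simulated data alone. They are not read as the power of the fits over all 17 arrays. There, several larger differences between stem and epithelial arrays missed the threshold.

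The alternatives were the donor as a fixed or random block, the batch as a block, the arrays of donors E and F alone, no background subtraction, an offset of 10, median scaling, cyclic loess, no filter, a filter on all arrays, probes of all species, the median of the spots, eBayes with trend and robust estimation, a fit of the compared groups alone, the series value table, each array left out in turn, and a limit of 1 background SD for the array measure. Added after seeing the data were the negative control limit as a filter, limma arrayWeights, the batch of 4 epithelial arrays and 1 stem array alone, and several of these without the stem array of donor A. Control spots, probes with blank names and the array with the conflicting label were left out of the comparisons.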

Results

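The data are 18 microRNA arrays of RNA from the prostate of human donors. The labels give 3 cell types, called normal epithelial, normal stem and stromal, and 17 of the arrays carry the number of 1 of 6 donors, written here as A to F. Epithelial and stromal RNA of all 6 donors was analysed (n = 6 arrays each), and stem RNA of 5 of them (A, B, D, E and F, n = 5). 1 further array carries a label whose parts name different groups, and it entered no comparison. Each array carries 9792 spots, with 4 spots for each of 569 human microRNA probes, and its Hy3 channel was read as fluorescence intensity. Each cell type of a donor was hybridised to 1 array, and the number of arrays limits the precision of each value.

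Stromal arrays were dimmer than epithelial arrays. The 90th percentile of the human probe signal was 1039 ± 216 intensity units on stromal arrays and 2948 ± 1449 on epithelial arrays (mean ± SD, n = 6 each, exact two-sided permutation p = 0.00216, Benjamini-Hochberg adjusted p = 0.00649 over 3 comparisons). On stem arrays it was 2083 ± 1445 (n = 5), and neither the test against stromal arrays (exact permutation p = 0.0887, adjusted p = 0.133) nor that against epithelial arrays (exact permutation p = 0.342) passed. The median raw intensity was 343.9 ± 27.9 on stromal, 433.7 ± 43.9 on epithelial and 448.6 ± 31.9 on stem arrays. Stromal arrays differed in it from epithelial arrays (exact permutation p = 0.00433, adjusted p = 0.00649) and from stem arrays (exact permutation p = 0.00216, the smallest that this design allows, adjusted p = 0.00649), while stem and epithelial arrays did not pass the test (exact permutation p = 0.532). The number of human probes above the local background averaged 432.3 on epithelial, 466.4 on stem and 509 on stromal arrays, and no pair of groups passed the exact permutation test (p = 0.134 for stromal against epithelial, 0.578 for stem against epithelial and 0.485 for stem against stromal). That rule was lenient, since the negative control probes often passed it. Against the negative control limit of each array, 169.5 ± 27.7 probes were counted on epithelial, 152.6 ± 80.5 on stem and 130.2 ± 17.9 on stromal arrays, and the adjusted exact permutation p was 0.0649 for stromal against epithelial.

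The stem array of donor A stood apart from all others. It showed 13 human probes above its negative control limit, against 111 to 209 on the other 17 arrays. Its correlation with the other compared arrays was 0.262 to 0.469 across human probes, while these correlated with each other at 0.726 or more, and probes are not independent replicates. It enters the values below because the comparisons were fixed before the data were examined, and values without it, a choice made after seeing the data, are given where they change a call of a named probe or list or move a named fold by over 1.5 times. The 17 compared arrays fell into 5 batches by scan. 1 batch held all cell types of donors E and F, 1 held 4 epithelial arrays and 1 stem array, 1 held 4 stromal arrays, and the remaining stem arrays of donors A and D each made a batch of their own. By the file headers these stem arrays of donors A and D also belonged to another array lot than all other arrays. Control names differed between the lots at 216 positions, all of them spike-in, empty or negative control. In the batch of donors E and F the median raw intensity averaged 370.5 on stromal, 403 on epithelial and 437.5 on stem arrays, and the 90th percentile of the human signal averaged 1012 on stromal, 2148 on epithelial and 3004 on stem arrays (n = 2 each). No other batch held stromal arrays together with another cell type.

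**Figure D1:**
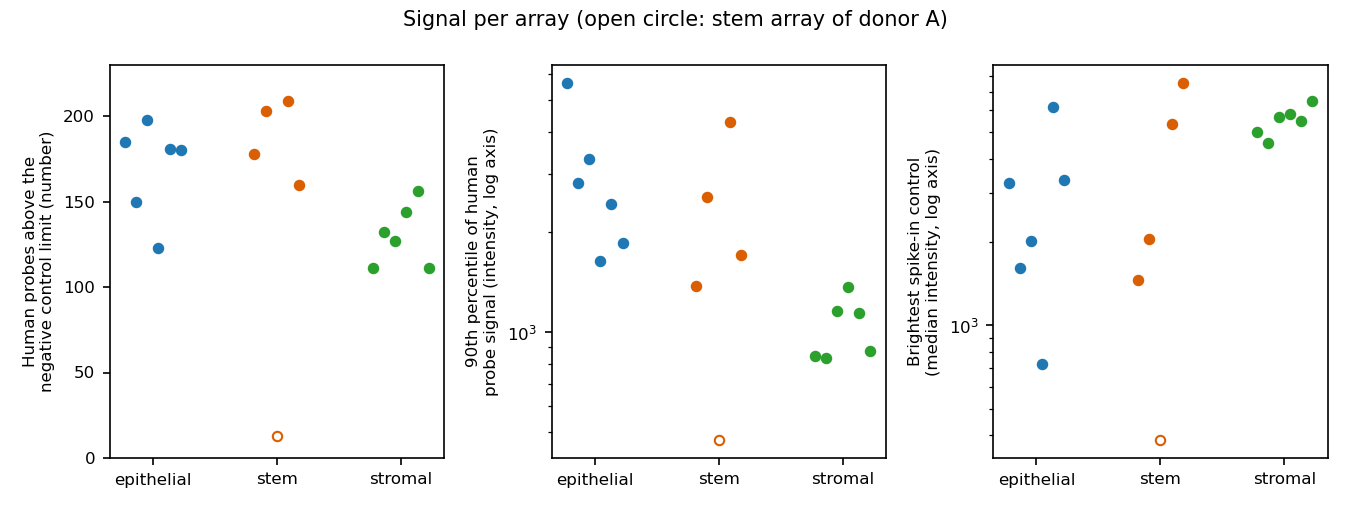
Number of human probes above the negative control limit, 90th percentile of the human probe signal and intensity of the brightest spike-in control by cell type, with 1 point for each of the 17 compared arrays and log axes for both intensities. The stem array of donor A has 13 human probes above the negative control limit, and the other stem arrays have 160 to 209.

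The comparison of stromal with epithelial arrays asks which microRNAs differ between stroma and epithelium of the same donors. Stroma carried more of the microRNAs known from fibroblasts and smooth muscle: miR-143, miR-199a and miR-214 were at or near background in epithelial cells and among the bright probes in stroma, higher in 6 of 6 donors. Epithelium carried more of the miR-200 family and miR-205, which are abundant in epithelial cells and repress the transcription factors ZEB1 and ZEB2. miR-125b and miR-100, encoded in a shared cluster, were also higher in stroma, by 11.0-fold and 8.84-fold. Of 557 human probes tested with limma, 49 were higher and 18 lower in stroma at an adjusted p under 0.05. Of these 67 calls, 42 were on probes above the negative control limit on at least 5 arrays.

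Among the fibroblast and mesenchymal microRNAs, 8 of 12 tested probes were higher in stroma over all probes tested and 10 adjusted over the list alone, and none was lower (camera adjusted p = 3.64e-12, and adjusted p = 0.0141 with an estimated correlation). miR-143, abundant in smooth muscle and fibroblasts, was higher by 4.33 on the log2 scale (SE 0.37, adjusted p = 2.63e-07), which is at least 14.3-fold because the epithelial mean lay under the negative control limit. miR-199a-5p, above that limit on 1 of 6 epithelial arrays, was at least 15.3-fold higher (log2 difference 4.19, SE 0.17, adjusted p = 1.69e-11). The other arm, miR-199a-3p, was at least 14.4-fold and at least 4.81-fold higher on its probes, and miR-214, transcribed from the same locus as a miR-199a gene, at least 8.67-fold. miR-145, which shares a primary transcript with miR-143, differed by 0.58 (adjusted p = 0.0209), and no fold is given because both group means were under the negative control limit.

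Among the epithelial microRNAs, 8 of 11 were lower in stroma over all probes and 10 adjusted over the list alone (camera adjusted p = 7.99e-11, and adjusted p = 0.0453 with an estimated correlation). Without the stem array of donor A 10 were lower and 1 was higher over all probes. miR-141, above the limit on 5 of 6 stromal arrays, was 9.99-fold lower (log2 difference -3.32, SE 0.59, adjusted p = 0.000939), miR-205, above it on 4 of 6, 6.82-fold lower (-2.77, SE 0.49, adjusted p = 0.000939), and miR-200a, miR-200b and miR-200c lay at -2.81, -2.88 and -2.80, each lower in 6 of 6 donors. miR-429 was at least 1.38-fold and miR-182 at least 1.24-fold lower. With median scaling miR-429 and miR-182 stayed lower without passing the test (-0.58 with adjusted p = 0.0737, and -0.48 with adjusted p = 0.123). miR-200c lay above the limit on 4 of 6 stromal arrays and averaged 9.68 ± 0.93 in stroma against 12.48 ± 0.12 in epithelium (log2 intensity, SD, n = 6 each). Outside the lists, miR-184, miR-302c* and miR-135b were lower in stroma (log2 differences of -1.41, -1.40 and -0.97), and miR-193a-3p was 3.12-fold higher. Their adjusted p-values were 0.0378, 0.0225, 0.00176 and 0.000186. With the donor as a block miR-184 missed the threshold (adjusted p = 0.0730). miR-184, miR-302c* and miR-135b missed it with the batch as a block (adjusted p = 0.0653, 0.15 and 0.104), while within the batch of donors E and F each passed it (limma adjusted p = 0.00565, 0.00911 and 0.0182). The arrays of donors E and F also entered the fit that picked these probes, so passing there is not independent support. With each of the 17 arrays left out in turn, 10 arrays ended the call of miR-184 (adjusted p up to 0.0919, without the epithelial array of donor C) and 5 that of miR-302c* (up to 0.0626, without the same array).

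At the preset correlation between probes 3 further lists were higher in stroma, and none of them with an estimated correlation over all 17 arrays. Of the imprinted cluster at 14q32, 13 of 41 members were higher and none lower, 15 adjusted over the list alone (camera adjusted p = 2.99e-05, and adjusted p = 0.0786 with an estimated correlation, which was 0.0478 without the stem array of donor A, with 19 members higher). miR-377 was at least 2.05-fold and miR-337-5p at least 1.98-fold higher. With only the probes above background on all arrays the list missed the threshold (adjusted p = 0.239). Most of the 41 members exceeded the negative control limit on no stromal array, so part of this shift lies near background. In the family of miR-99, miR-100 and miR-125, 2 of 5 were higher over all probes and 4 adjusted over the list alone (camera adjusted p = 0.00398, and adjusted p = 0.210 with an estimated correlation). That shift did not pass with median scaling (adjusted p = 0.123) or in the series value table (0.263). let-7i was 3.95-fold higher (log2 difference 1.98, adjusted p = 0.000114) and was the only called member of the let-7 family, whose shift did not pass (camera adjusted p = 0.955), and in the series value table the list passed towards lower values (adjusted p = 0.0476). In the list of miR-15, miR-16 and the X-linked cluster, 3 of 8 were higher and 6 adjusted over the list alone, but with median scaling the shift of the list pointed the other way (camera adjusted p = 0.992). It also missed the threshold with the donor as a random block (0.122), with limma arrayWeights (0.0696), with only the compared groups in the fit (0.0945), with cyclic loess (0.0786), in the series value table (0.686) and with the negative control limit as the filter (0.338). Examples were miR-15b at 1.25 (adjusted p = 0.0329) and miR-450a at 0.74 (adjusted p = 0.00178). That list had a camera adjusted p of 0.0343, an adjusted p = 0.128 with an estimated correlation, an adjusted p = 0.0800 without the stem array of donor A and an adjusted p = 0.0731 without the stromal array of donor E. miR-15b was lower by its value in the series table (log2 difference -0.33, adjusted p = 0.813), and 8 of the 17 arrays ended its call when left out (adjusted p up to 0.0893, without the stromal array of donor D).

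By camera at the preset correlation the lists for other cell types did not shift. With fry, planned beside it, the muscle, blood cell and nerve cell lists passed (fry adjusted p = 0.0443, 0.0291 and 0.0443). Muscle microRNAs had 0 of 7 calls over all probes and 5 adjusted over the list alone (camera adjusted p = 0.104, and adjusted p = 0.0376 without the stromal array of donor F). In the series value table and with probes of all species they passed towards higher values (adjusted p = 0.0140 and 0.0180). miR-206 averaged 10.85 ± 2.18 in stroma and 8.69 ± 0.28 in epithelium, with an adjusted p of 0.0716, and of 0.0415 without the stem array of donor A. Blood cell microRNAs had 1 of 7 higher, miR-155 at 0.94 (adjusted p = 0.00921), with a camera adjusted p of 0.303. Nerve cell microRNAs had none of 6 called (camera adjusted p = 0.40), and the pluripotency microRNAs, the miR-17-92 cluster with its paralogs, the families of miR-29 and miR-30 and the clusters of miR-23, miR-27 and miR-24 had no call (camera adjusted p = 0.841, 0.40, 0.0899 and 0.40). If the stem array of donor A is left out, 4 blood cell, 2 nerve cell, 2 pluripotency and 1 muscle microRNAs were higher. Of the miR-29 and miR-30 families 1, miR-29a, was then higher (adjusted p = 0.000960) and 2 were lower. The list of miR-29 and miR-30 passed without the epithelial array of donor F (adjusted p = 0.0477) and without the stromal array of donor F (adjusted p = 0.0464). With median scaling the lists of miR-17-92, of miR-29 and miR-30 and of the miR-23 clusters passed towards lower values (adjusted p = 0.0110, 5.41e-07 and 7.32e-05). In the series value table the first 2 did so (0.0168 and 0.00849), and without the stem array of donor A the miR-23 clusters did too (0.00219). For the pluripotency and miR-17-92 lists the median lay above 0 (0.07 and 0.01) while the test pointed to lower values. Their members with the largest differences were miR-371-5p at -0.71, miR-20b at -0.31, miR-29a at 1.04 and miR-27a at -0.29, with adjusted p-values of 0.283, 0.320, 0.260 and 0.715. The lists of miR-34, miR-221 with miR-222 and the endothelial miR-126 had 2 tested members each and no call, which is too few for the list test. Leaving out the stem array of donor A made 1 call of miR-34 and 1 of miR-221 with miR-222, both higher. miR-21, among the brightest probes in both cell types, differed by -0.39 (SE 0.79, adjusted p = 0.778), and it was saturated on 1 of 6 epithelial arrays.

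Without the stem array of donor A, which enters this comparison through the shared spread, 118 probes were higher and 42 lower, and all 67 earlier calls were among them with the same direction. Without the stromal array of donor A 59 were higher and 31 lower, and without the epithelial array of donor B 50 were higher and 33 lower. Median scaling put the median of all probes 1.05 higher in stroma on the log2 scale and called 387 higher and 29 lower, so the values above are relative to the bulk of the probes. The series value table called 19 higher and 22 lower, and in it miR-125b, let-7i and miR-193a-3p missed the threshold (log2 differences of 2.21, 0.26 and 0.13, adjusted p = 0.111, 0.848 and 0.957). A block for the batch left 23 higher and 12 lower, and 29 of the 67 calls were among them with the same direction. Within the batch of donors E and F 23 were higher and 23 lower, and 30 of the 67 were among them. The 4 stromal arrays of donors A to D share a batch with no other cell type, so the batch block gives them no weight in the difference. Both fits thus take their stromal values from donors E and F, whose arrays also entered the calls. They are not separate checks. The adjusted camera p-values with the batch as a block were 4.48e-11 for the fibroblast list, 5.62e-11 for the epithelial list, 0.000352 for 14q32, 0.00243 for the miR-99 family and 0.103 for the miR-15 list. Within the batch of donors E and F they were 3.32e-08, 4.68e-12, 0.000496, 0.00489 and 0.0646.

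**Figure D2:**
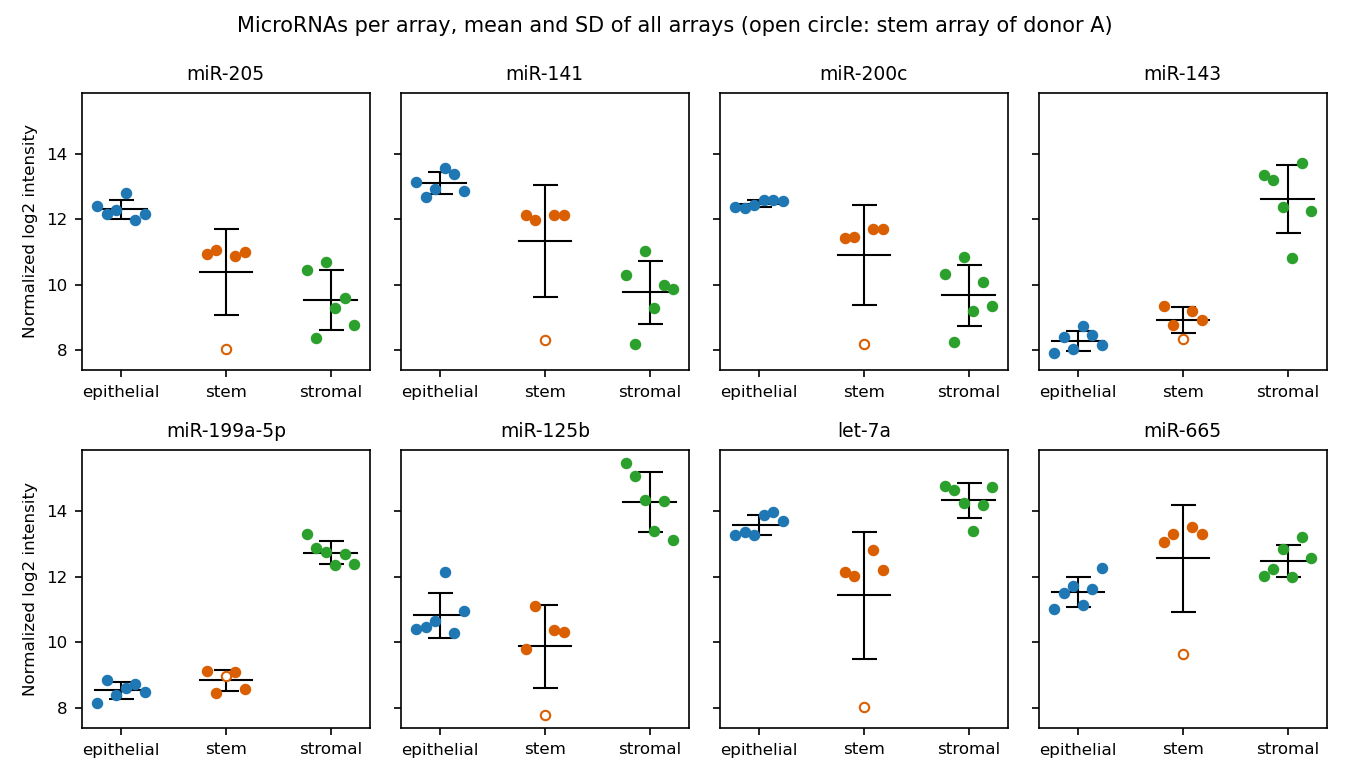
Normalised log2 intensity of named microRNAs on each of the 17 compared arrays, with 1 point per array, the group mean as a bar and the SD as the error bar. miR-143 averages 12.62 in stroma and 8.29 in epithelium, and miR-205 9.53 and 12.30.

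The comparison of stem with epithelial arrays asks how the cells labelled stem differ from the epithelium of the same donors. Few microRNAs passed the test over all 17 arrays. miR-877, above the negative control limit on 2 of 6 epithelial arrays, was at least 1.80-fold higher in stem cells (log2 difference 1.10, SE 0.24, limma adjusted p = 0.0244). It was higher in 5 of 5 donors, which the rule for named probes required. miR-19b, a member of the miR-17-92 cluster that promotes proliferation, was 2.94-fold lower (log2 difference -1.56, SE 0.37, limma adjusted p = 0.0434). It was above the limit on 4 of 5 stem arrays. The size for miR-19b leans on the stem array of donor A, at 8.77 against 10.82 on the next lowest stem array. Without the stem array of donor A, the let-7 microRNAs let-7a, let-7b and let-7c, the collagen-repressing miR-29a and the epithelial miR-205 were lower in stem cells, and miR-765, miR-583, miR-483-5p and miR-665 were higher. None of the 12 fibroblast probes was called, and miR-143 lay at 8.92 ± 0.39 in stem cells (log2 intensity, SD, n = 5) against 8.29 ± 0.31 in epithelium (n = 6, limma adjusted p = 0.384). It was above the negative control limit on 4 of 5 stem and 0 of 6 epithelial arrays. In stem cells it was higher for donors B, D, E and F and lower for donor A.

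Of 557 probes, 4 were higher and 5 lower in stem cells over all 17 arrays, and 13 were higher and 14 lower without the stem array of donor A, with all 9 earlier calls among them. Higher over all 17 arrays were miR-877, miR-596 (at least 1.19-fold), miR-185 (1.74-fold) and miR-433 (log2 difference 0.48), and lower were miR-19b, miR-629*, miR-32, miR-151-5p and miR-361-5p. The last 4 differed by -0.68, -0.67, -0.61 and -0.58, but their stem means lay under the negative control limit, with 0, 1, 1 and 4 of 5 stem arrays above it. As bounds miR-32 was at least 1.13-fold and miR-361-5p at least 1.07-fold lower, while miR-629* and miR-151-5p allow no bound above 1. The largest higher values without the stem array of donor A were miR-765 at 2.39 (SE 0.46, adjusted p = 0.00515), miR-583 at 1.95 (SE 0.24, adjusted p = 0.000246), miR-483-5p at 1.93 (adjusted p = 0.00757) and miR-665 at 1.83 (adjusted p = 0.000831). With that array miR-765, miR-583, miR-483-5p and miR-665 lay at 1.76, 1.39, 1.25 and 1.02 (adjusted p = 0.0833, 0.0697, 0.189 and 0.328). On the lower side let-7a, let-7b and miR-29a lay at -2.14, -1.95 and -2.01 with it (adjusted p = 0.0709, 0.0532 and 0.0764). The largest lower values without it were miR-205 at -1.40 (SE 0.37, adjusted p = 0.0371), let-7b at -1.33 (adjusted p = 0.00227), let-7a at -1.32 (adjusted p = 0.00515) and miR-29a at -1.18 (adjusted p = 0.00422), each lower in 4 of 4 donors. miR-205 missed the threshold with the batch as a block as well (adjusted p = 0.181). The rule for the largest values required the same sign in every donor.

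By list, more microRNAs were lower than by the single calls, but only at the preset correlation of 0.01. With an estimated correlation none of these lists passed. The estimates were 0.210 for miR-17-92, 0.709 for miR-29 and miR-30, 0.237 for let-7, 0.436 for the epithelial list and 0.963 for the miR-23 clusters. In the miR-17-92 cluster and its paralogs 1 of 14 members was lower over all probes and 9 adjusted over the list alone (camera adjusted p = 4.25e-05, and adjusted p = 0.273 with an estimated correlation), with miR-106a at -1.37 and miR-20a at -1.25. In the families of miR-29 and miR-30 none of 8 passed over all probes and 6 were lower adjusted over the list alone (camera adjusted p = 3.51e-05, and adjusted p = 0.273 with an estimated correlation). Of the let-7 family, which accumulates in differentiated cells, none of 9 passed over all probes, and 6 were lower and 1, let-7e, higher adjusted over the list alone (camera adjusted p = 0.00122, and adjusted p = 0.273 with an estimated correlation). Of the epithelial microRNAs none of 11 passed and 5 were lower adjusted over the list alone (camera adjusted p = 0.00104, and adjusted p = 0.288 with an estimated correlation), with miR-205 at -1.92, miR-141 at -1.76 and miR-200c at -1.58. With the stem array of donor A left out, 1 epithelial microRNA, miR-205, was lower adjusted over the list alone. miR-141 and miR-200c then lay at -1.05 and -0.95. With the donor as a block and without that array the list missed the threshold (adjusted p = 0.0577), as it did with the negative control limit as the filter and without that array (0.0966) and with limma arrayWeights (0.0923). The clusters of miR-23, miR-27 and miR-24 had 4 of 5 lower adjusted over the list alone (camera adjusted p = 0.00579, and adjusted p = 0.326 with an estimated correlation), and without the stem array of donor A none and an adjusted p of 0.0775, with 0.106 for limma arrayWeights. Without that array the other adjusted camera p-values were 6.63e-05 for miR-17-92, 7.61e-05 for miR-29 and miR-30, 0.00359 for let-7 and 0.0151 for the epithelial list. With fry over all 17 arrays the epithelial list and the miR-23 clusters missed the threshold (fry adjusted p = 0.0595 and 0.0943). Cyclic loess ended the shift of let-7 (camera adjusted p = 0.0694) and of the miR-23 clusters (0.118). With only the probes above background on all arrays the epithelial, let-7 and miR-23 lists missed the threshold (0.342, 0.149 and 0.149). With the negative control limit as the filter let-7 and miR-23 did (0.0735 and 0.113).

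The pluripotency microRNAs, which mark embryonic stem cells, showed no shift (camera adjusted p = 0.380), and their member with the largest difference, miR-371-5p, lay at 0.81 (SE 0.44, adjusted p = 0.338). The lists of fibroblast, muscle, 14q32, blood cell and nerve cell microRNAs had camera adjusted p-values of 0.138, 0.380, 0.0824, 0.380 and 0.0564, with 1 call among them, miR-433 of 14q32. The nerve cell list passed without the stem array of donor D (adjusted p = 0.0404), and likewise without the stem array of donor F, the epithelial array of donor C or D, or the stromal array of donor B (0.0444, 0.0488, 0.0386 and 0.0482). Over all 17 arrays it passed with no background subtraction (0.0492) and with eBayes with trend and robust estimation (0.0477). For the lists of miR-15 with miR-16 and of miR-99, miR-100 and miR-125 they were 0.117 and 0.0824. With the donor as a block the miR-15 list passed (adjusted p = 0.0335), and without the stem array of donor D the miR-99 list did (adjusted p = 0.0335). Median scaling and probes of all species also brought the miR-99 list past it, towards lower values (adjusted p = 0.0247 and 0.0388), and the negative control limit as the filter the fibroblast list, towards higher ones (0.0402). In the series value table the miR-99 and miR-15 lists passed as lower (0.0482 and 0.0257) and the 14q32, muscle and nerve cell lists as higher (0.00239, 0.0276 and 0.0257). The lists of miR-34, miR-221 with miR-222 and miR-126 had no call among 2 tested members each. miR-21 lay at -2.23 over all 17 arrays (SE 0.83, adjusted p = 0.129) and at -1.0 without the stem array of donor A (adjusted p = 0.0321). It was saturated on 1 epithelial and 1 stem array, so the size of these differences is uncertain.

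The count depended on single arrays and on keeping the stromal arrays in the fit. With only stem and epithelial arrays in it, 0 probes were higher and 0 lower (99 at an unadjusted limma p under 0.05). Besides the stem array of donor A, leaving out the epithelial array of donor C left 1 higher and 0 lower, that of donor A 2 and 4, that of donor B 2 and 3, that of donor D 1 and 1, and that of donor E 2 and 2. Leaving out the stem array of donor B left 1 and 1, that of donor D 4 and 2, and that of donor E 4 and 14. miR-19b lost its call without any of 12 arrays (adjusted p up to 0.0997, without the epithelial array of donor B), miR-185 without any of 10 (up to 0.0879, stem array of donor F) and miR-361-5p without any of 7 (up to 0.0868, epithelial array of donor D). For miR-877 there were 5 such arrays (up to 0.0674, epithelial array of donor B), for miR-433, miR-32 and miR-151-5p 4 each (up to 0.0624 and 0.0609 without the epithelial array of donor C and 0.0682 without that of donor D), and for miR-629* 1 (adjusted p = 0.0519, epithelial array of donor C). With the donor as a block 6 were higher and 33 lower, among them let-7a, let-7b, miR-106a and miR-20a (adjusted p = 0.0331, 0.0311, 0.0201 and 0.00881). Median scaling called 4 higher and 17 lower with the median of all probes at 0.34, cyclic loess 19 higher and 12 lower, and the series value table none of 556, with 115 at an unadjusted limma p under 0.05. With the batch as a block, which gives the lone stem arrays of donors A and D no weight, 13 were higher and 4 lower, with 6 of the 9 calls among them, and miR-19b, miR-32 and miR-361-5p missed the threshold (adjusted p = 0.0638, 0.148 and 0.162). Within the batch of donors E and F 3 were higher and 0 lower (53 at an unadjusted limma p under 0.05), and none of the 9 calls passed in this fit of 6 arrays (adjusted p from 0.207 for miR-877 to 0.810 for miR-361-5p). All 9 kept their direction there, but they were called on arrays that include those of donors E and F. Their direction was thus partly fixed by the choice. miR-877, miR-596, miR-185 and miR-433 lay at 0.72, 0.74, 0.87 and 0.58, and the lower ones from -0.82 for miR-19b to -0.34 for miR-32. miR-583 and miR-765 passed there (log2 differences of 1.68 and 1.40, limma adjusted p = 0.0341 and 0.0341). They too were picked on arrays that include these, so their values there cannot decide whether batch took part. The batch of 4 epithelial arrays and 1 stem array gave 5 and 0 (55 at an unadjusted limma p under 0.05). Its spread comes from the epithelial arrays alone, so these calls assume that the lone stem array varies like them and are not read as support. The adjusted camera p in the fit with the batch was 0.00285 for miR-17-92, 0.00895 for miR-29 and miR-30, 0.00626 for let-7, 0.102 for the epithelial list and 0.192 for the miR-23 clusters. Within the batch of donors E and F these were 0.00824, 0.000968, 0.00852, 0.000968 and 0.123. Within the other batch they were 0.00445, 0.222, 0.00445, 0.00670 and 0.396, under the same assumption about its lone stem array, and are not read as support either.

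The comparison of stem with stromal arrays asks how the cells labelled stem differ from the stroma of the same donors. Stem cells carried far less of the stromal microRNAs than stroma. miR-125b, above the limit on 4 of 5 stem arrays, was 21.2-fold lower than in stroma (log2 difference -4.41, SE 0.54, adjusted p = 1.96e-05), miR-199a-5p at least 11.2-fold (adjusted p = 1.18e-10), miR-143 at least 9.29-fold (adjusted p = 3.70e-06) and miR-214 at least 6.93-fold (adjusted p = 5.32e-09), each lower in 5 of 5 donors. The last 3 were above the limit on 2, 4 and 1 of 5 stem arrays, with stem means under it. Without the stem array of donor A, stem cells carried more of the miR-200 family: miR-141 was 5.40-fold higher than in stroma (log2 difference 2.43, SE 0.39, adjusted p = 0.000268) and miR-200c 3.98-fold (adjusted p = 0.000721), above the limit on 5 and 4 of 6 stromal arrays. With that array miR-141 and miR-200c lay at 1.56 and 1.22 (adjusted p = 0.0913 and 0.148).

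Of the fibroblast and mesenchymal microRNAs 9 of 12 were lower in stem cells, and 9 adjusted over the list alone (camera adjusted p = 4.27e-09, and adjusted p = 0.0455 with an estimated correlation, which was 0.141 without the stem array of donor A). Of the miR-99, miR-100 and miR-125 family 4 of 5 were lower, as many adjusted over the list alone, with miR-100 at -3.54 (camera adjusted p = 0.000386, and adjusted p = 0.166 with an estimated correlation). Of the list of miR-15, miR-16 and the X-linked cluster 5 of 8 were lower and 6 adjusted over the list alone (camera adjusted p = 0.00449, and adjusted p = 0.0704 with an estimated correlation), with miR-15b at -2.07 and miR-16 at -1.70. Of the 14q32 cluster 10 of 41 were lower and 2 higher, 11 and 2 adjusted over the list alone (camera adjusted p = 0.0181, and adjusted p = 0.311 with an estimated correlation), with miR-377 at least 1.74-fold lower. Most of the 41 members exceeded the negative control limit on no stromal array. Leaving out the stem array of donor A, 17 members of 14q32 were lower and 3 higher. With the batch as a block its list then had an adjusted p of 0.0505, and with the negative control limit as the filter of 0.0596. Median scaling ended the shift of the miR-15 list (adjusted p = 0.188) and, without the stem array of donor A, also that of the miR-99 family (0.0676). In the series value table without that array both missed the threshold (0.151 and 0.0901). With only the probes above background on all arrays the miR-15 and 14q32 lists missed it (0.161 and 0.276). With the negative control limit as the filter the miR-15 list did (0.154).

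Of the let-7 family 6 of 9 were lower and 1, let-7e, higher, but the list pointed the other way in the series value table without the stem array of donor A (adjusted p = 0.842). Adjusted over the list alone 7 were lower and 1 higher (camera adjusted p = 0.0244, and adjusted p = 0.311 with an estimated correlation). let-7i lay at -2.69 (adjusted p = 4.60e-06) and let-7a at -2.89 (adjusted p = 0.00340). Once the stem array of donor A is left out, let-7a lay at -2.05 (adjusted p = 1.23e-05). Of the miR-17-92 cluster and its paralogs 6 of 14 were lower, but in that table without that array the list pointed the other way (adjusted p = 0.923), with miR-17 at 0.04. Over all 17 arrays miR-17 lay at -1.34, and as many members were lower adjusted over the list alone (camera adjusted p = 0.0195, and adjusted p = 0.311 with an estimated correlation). The let-7 and miR-17-92 lists missed the threshold without the stem array of donor A (adjusted p = 0.0813 and 0.0652), and miR-17-92 with the donor as a random block (0.0819). Both also missed it with median scaling (0.125 and 0.334), in the series value table (0.881 and 0.806) and with the negative control limit as the filter (0.0668 and 0.0668). miR-221 and miR-222, which share a cluster and repress the cell cycle inhibitor p27, were lower (log2 differences of -1.55 and -1.27, adjusted p = 0.00364 and 0.0126), except that miR-222 was not lower in the series value table without the stem array of donor A (0.20, adjusted p = 0.927). miR-29a, at -3.05 (adjusted p = 0.00214) and at -2.19 without the stem array of donor A (adjusted p = 1.36e-06), was the only called member of its list, 4 of 8 adjusted over the list alone (camera adjusted p = 0.112, and adjusted p = 0.0165 without the stem array of donor B and 0.0129 with probes of all species, both lower). miR-34a was lower as well (-1.97, adjusted p = 0.00486), and the endothelial miR-126 had no call among 2 tested probes.

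Of the epithelial microRNAs 2 of 11, miR-182 and miR-429, were higher in stem cells than in stroma and 3 adjusted over the list alone (camera adjusted p = 0.000157, and adjusted p = 0.235 with an estimated correlation). Without the stem array of donor A 9 were higher (camera adjusted p = 1.82e-07, and adjusted p = 0.148 with an estimated correlation). Of the called probes that were higher in all 5 donors over all 17 arrays, those with the largest differences were miR-671-5p at 1.75, miR-498 at 1.59, miR-371-5p at 1.51 and miR-877 at 1.29, with adjusted p-values of 0.00241, 0.0112, 0.0218 and 0.00114. miR-671-5p, miR-498 and miR-371-5p were above the negative control limit on 5 of 5 stem arrays. They were thus among the 13 human probes above it on the stem array of donor A, which carried little other microRNA signal. miR-371-5p was the only called pluripotency microRNA, and that list did not shift (camera adjusted p = 0.437, with a median of -0.03 while the test pointed to higher values). Without 1 of 4 arrays miR-371-5p missed the threshold (adjusted p up to 0.0529, stromal array of donor B), and miR-429 without 1 of 7 (up to 0.103, stem array of donor F). In the fit with the batch as a block miR-671-5p, miR-498, miR-371-5p, miR-221 and miR-222 missed it (adjusted p = 0.0694, 0.120, 0.158, 0.0573 and 0.196). The muscle, blood cell and nerve cell lists and the miR-23 clusters did not shift either (camera adjusted p = 0.324, 0.597, 0.456 and 0.165), and the median of the nerve cell list was -0.07 while its test pointed to higher values. With median scaling and no stem array of donor A the miR-23 clusters passed towards higher values (adjusted p = 0.0459), and with probes of all species towards lower values (0.0349).

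Of 557 probes tested, 33 were higher and 76 lower in stem cells than in stroma over all 17 arrays, and without the stem array of donor A 60 of 168 calls were higher, with 102 of the former calls among them. Leaving out the stromal array of donor D left 18 higher and 59 lower, that of donor B 21 and 63, and that of donor F 21 and 67. Leaving out the stem array of donor D left 21 and 69, that of donor E 21 and 62, and that of donor F 22 and 73. Median scaling called 13 higher and 39 lower with the median of all probes at -0.75, and without the stem array of donor A 34 of 458 calls were higher with that median at -1.08. Cyclic loess called 41 higher and 55 lower, and 3 were higher and 18 lower in the series value table. A block for the batch left 25 higher and 41 lower, and 53 of the calls over all batches were among them. Within the batch of donors E and F 45 were higher and 40 lower, and 64 of the calls over all batches were among them. Here too the batch block gives the stromal arrays of donors A to D no weight in the difference. Both fits take their stromal values from donors E and F, whose arrays also entered the calls, and are not separate checks. With the batch as a block the adjusted camera p was 2.19e-07 for the fibroblast list, 3.21e-07 for the epithelial list, 0.00323 for the miR-99 family, 0.0410 for the miR-15 list, 0.0488 for 14q32, 0.0724 for miR-17-92 and 0.147 for let-7. Within the batch of donors E and F these were 5.73e-06, 5.00e-08, 0.00635, 0.0344, 0.0146, 0.0405 and 0.116.

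**Figure D3:**
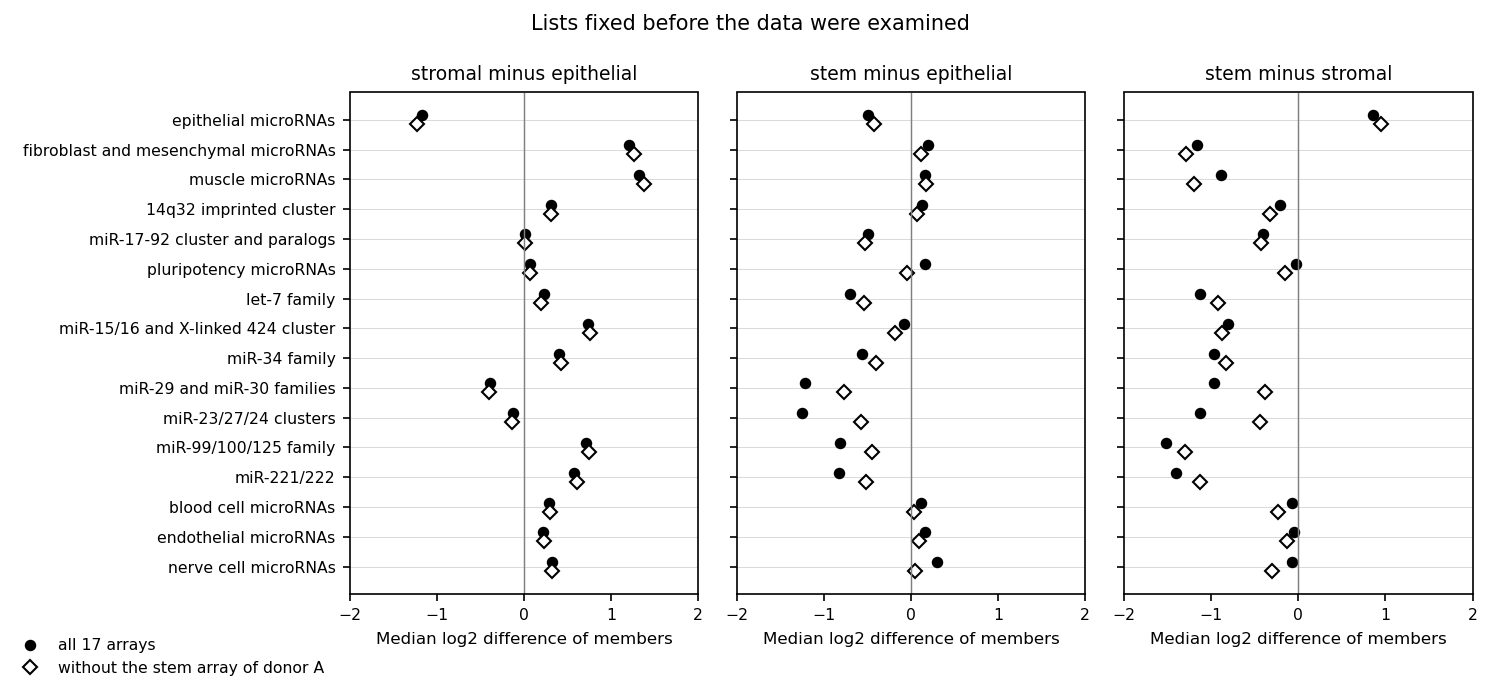
Median log2 difference of the tested members of each fixed microRNA list in the 3 comparisons, over all 17 arrays and without the stem array of donor A, 1 point per list and fit. The fibroblast list lies at 1.21 and the epithelial list at -1.18 for stromal minus epithelial over all 17 arrays.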

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

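The spike-in, RNA amount and negative control tests of the stem array of donor A and both tests of the array batch were chosen only after the result was seen. Of 132 groups of values read for an array far from the rest of its group, 21 held such an array, and chance gives about 1 in 20 groups. In 15 of the 21 it was the stem array of donor A.

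The stem array of donor A had 13 human probes above its negative control limit, against 160 on the next lowest stem array. It had the lowest normalised value of the stem arrays for miR-141 (8.30), miR-200b (8.86), miR-200a (7.97), miR-200c (8.20), miR-205 (8.04), miR-184 (8.19), miR-222 (9.56), miR-21 (8.0), let-7a (8.02), miR-19b (8.77), miR-361-5p (8.32) and miR-29a (8.04), and the highest for miR-145 (9.15) and let-7e (11.30), in log2 intensity. The 90th percentile of its human signal was 474, under its negative control limit of 584. Quantile normalisation gave this array the same distribution as the others, so these values are not read as microRNA levels. Labelling or hybridisation may have failed on this array, since its brightest spike-in control had a median of 384.5, below the 724 to 7530 of the other 17 arrays. The only other array of the same array lot, the stem array of donor D, had 1454.5, and control names differed between the lots at 216 positions. Too little RNA with intact labelling stays open, because the spike-in signal of the stem array of donor A was 0.531 of the lowest other array and no file states which samples received spike-in RNA. A scan that dimmed the whole array is argued against, because the median signal of its negative control spots was 282, above the 67 to 219.5 of the other arrays. The planned test on its Hy3 landmark spots was void, since 85% of them were saturated. No biological explanation was tested.

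The mean of the epithelial miR-141, miR-200a, miR-200b, miR-200c and miR-205 differed between stromal arrays, from 8.26 for donor B to 10.98 for donor C. Array batch is argued against as the whole cause, because the mean ranged over 0.563 in the batch with stromal arrays of donors E and F and over 2.72 in the batch with those of donors A to D, both above 3 SD of the epithelial arrays (0.510). Epithelial cells in some stromal samples could raise these microRNAs, and the labels name no sort that would remove them. Over the 6 stromal arrays the mean correlated with that of the other probes brighter in epithelial cells, miR-184, miR-135b, miR-378 and miR-101, with r = 0.313 (exact two-sided permutation p = 0.546, adjusted p = 0.655 over 6 relations) and rho = 0.0857 (p = 0.919), and r = -0.438 without the 2 arrays farthest from the median, which leaves this open. A difference between donors in stromal cells themselves was not tested.

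A group of 13 probes was brighter on stem than on epithelial arrays without the stem array of donor A, among them miR-765, miR-583, miR-483-5p, miR-665, miR-877, miR-596 and miR-185. Quantile normalisation is argued against as the whole cause, because the median difference of the group was 1.11 with median scaling, against 0.932 with quantile normalisation. Within the batch of donors E and F the median difference was 0.742, and 13 of 13 probes lay above 0 each time. The probes were chosen as higher on stem arrays that include those of donors E and F. The value within that batch was thus partly fixed by the choice and cannot decide whether array batch took part. RNAs other than microRNAs that bind these probes could raise them, and they cannot be told apart from a change in the microRNAs. Over the 6 epithelial arrays the group correlated with the U6 and snoRNA control signal with r = -0.600 (exact two-sided permutation p = 0.240, adjusted p = 0.481 over 6 relations) and rho = 0.0857, but r was 0.633 without the 2 arrays farthest from the median, so the negative value rests on those arrays. Over the 6 stromal arrays r was -0.0948 (exact permutation p = 0.844), and without the stem array of donor A the control signal was 0.321 higher on stem than on epithelial arrays (exact permutation p = 0.219, adjusted p = 0.329 over 3 comparisons). A difference of the cells labelled stem, the group the design names, stays among the open explanations.

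The stromal array of donor E had 298 human probes above the local background, against 544 on the next lowest stromal array. miR-125b at 12.16 and miR-100 at 10.28 were highest, and miR-302c* at 9.05 and miR-671-5p at 12.06 lowest, on the epithelial array of donor B. let-7i was lowest on the stromal array of donor A, at 11.41. Outside the comparisons, the U6-snRNA-2 control had a median signal of 19334 over the 17 arrays, against 188.5 for the negative controls. In the second channel of the scanner 1 array had 229 spots above background, against 21 on the next.

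Other splits of the same arrays were compared with the real grouping, 100 splits each with the real one included. For stromal against epithelial arrays 67 probes were called and at most 18 in another split, and without the stem array of donor A 160 against 142. The real grouping was thus the highest of the 100 splits in both. The split with 142 exchanges the stromal array of donor A with the epithelial array of donor B. For stem against epithelial arrays 9 were called and at most 1 in another split, and without the stem array of donor A 27 against 7. The split with 7 sets the epithelial arrays of donors A to D apart from the others. These 4 epithelial arrays share a batch with the stem array of donor B, which is on the other side of that split. For stem against stromal arrays 33 higher and 76 lower were called. The split that places the stromal array of donor A with the stem arrays called 118, so 2 of 100 splits were as large. Without the stem array of donor A the counts were 168 against 146. The split with 118 differs from the real grouping in 1 stromal array and points to a structure of the samples. Among splits that part all donor pairs the highest count was 0 for stromal against epithelial arrays, and 0 without the stem array of donor A. It was 0 and 6 for stem against epithelial and 60 and 0 for stem against stromal arrays. Only 7 to 10 of the drawn splits part all donor pairs, and the draw took no account of batch. The splits therefore do not exclude chance.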

How the results depend on the processing

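The alternatives without the stem array of donor A beyond leaving it out alone, the negative control limit, arrayWeights and the batch of 4 epithelial arrays and 1 stem array were chosen only after seeing the data. Counts are given as higher and lower calls, and where a count moved the cause was not tested, unless fewer probes or fewer arrays were in the fit. Called lists kept their direction and their side of the threshold in 181 of 204 alternative values for stromal against epithelial, 187 of 210 for stem against epithelial and 251 of 286 for stem against stromal arrays, and named called probes in 1028 of 1086, 254 of 371 and 1687 of 1908. The difference in human probes above local background kept its side of the threshold with 1 SD in place of 2. Signal over background limits the dim microRNAs: 167 human probes passed the local background rule on all arrays, and folds against a group under the negative control limit are lower bounds. The log2 ratio to a second colour was not run because the second channel held signal on few spots.

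With the donor as a block (replicate block) stem against epithelial arrays gave 33 lower calls, and with a random replicate block 7 and 19. Among named results the block ended the calls of miR-184 for stromal against epithelial (adjusted p = 0.0730) and of miR-193a-5p, miR-483-5p and miR-96* for stem against stromal arrays (0.0529, 0.0703 and 0.0571). It brought further named probes past the threshold: 4 of 44 for stromal against epithelial, 13 of 77 for stem against epithelial and 4 of 37 for stem against stromal arrays. Of the lists it made 1 further call, miR-15 and miR-16 for stem against epithelial, and it changed no other call of a list or named probe. The random replicate block ended the calls of the miR-15 and miR-16 list for stromal against epithelial (adjusted p = 0.122) and of the miR-17-92 list for stem against stromal arrays (0.0819).

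With each array left out in turn, stromal against epithelial gave 33 to 118 higher and 12 to 42 lower calls, stem against epithelial 1 to 13 higher and 0 to 14 lower, and stem against stromal 18 to 60 higher, with 59 lower at the fewest. With the batch as a block stromal against epithelial gave 23 higher, stem against epithelial 13 higher and stem against stromal 41 lower calls. The batch of donors E and F alone gave 23 higher for stromal against epithelial, 0 lower for stem against epithelial (53 at an unadjusted limma p under 0.05) and 40 lower for stem against stromal, and the batch of 4 epithelial arrays and 1 stem array gave 0 lower for stem against epithelial (55 unadjusted), with the lone stem array assumed to vary like the epithelial ones. No background subtraction gave 10 lower for stem against epithelial, and eBayes with trend and robust estimation 2 lower. Median scaling gave 387 and 29 for stromal against epithelial, 17 lower for stem against epithelial and 13 and 39 for stem against stromal, and cyclic loess 19 and 12 for stem against epithelial.

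With probes above background on all arrays, which leaves 167, the counts were 16 and 9 for stromal against epithelial, 7 and 30 for stem against epithelial and 16 and 47 for stem against stromal. With the negative control limit, which leaves 195, stromal against epithelial gave 27 higher and stem against epithelial 25 lower. Probes of all species, 1896, gave 75 and 74, 15 and 8, and 144 and 129. Fits of the compared groups alone gave 94 and 38, 0 and 0 (99 at an unadjusted limma p under 0.05), and 19 higher for stem against stromal. The series value table gave 19 higher for stromal against epithelial, 0 and 0 for stem against epithelial (115 unadjusted), and 3 and 18 for stem against stromal. limma arrayWeights gave 134 and 57, 23 and 48, and 74 and 130.

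Without the stem array of donor A, the replicate block gave 119 and 54 for stromal against epithelial, 25 and 42 for stem against epithelial and 73 and 132 for stem against stromal. The random replicate block gave 127 and 55, 21 and 25, and 68 and 130. The batch as a block gave 23 higher, 13 higher and 41 lower calls. The negative control limit gave 41 lower, 15 and 25, and 52 higher. Median scaling gave 418 and 36, 10 and 14, and 34 higher of 458 calls, with 4.2e+02 lower. Cyclic loess gave 25 and 11 for stem against epithelial. The series value table gave 27 and 85 for stromal against epithelial, 0 and 0 for stem against epithelial (88 unadjusted), and 33 and 22 for stem against stromal.

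A few results pointed the other way in an alternative. With median scaling these were, for stromal against epithelial, miR-15 with miR-16 (list, adjusted p = 0.992) and miR-372 (0.90 on the log2 scale). With median scaling and no stem array of donor A they were that list again (0.898), miR-34c-5p (0.61) and miR-372 (0.90), and for stem against stromal the miR-23, miR-27 and miR-24 list (0.0459), miR-126* (-1.07), miR-34c-5p (-1.02), miR-371-3p (-1.11) and miR-486-5p (-1.06). Median scaling put the median of all probes at 1.05 for stromal against epithelial, with and without that array. For stem against stromal without it that median was -1.08. The turns of these single probes thus go with a shift of all probes. In the series value table the let-7 list (0.0476) and miR-15b (-0.33) turned for stromal against epithelial. In that table without the stem array of donor A, the let-7 list (0.0197), miR-15b (-0.33) and miR-17 (-1.65) turned for stromal against epithelial, and for stem against stromal the let-7 list (0.842), the miR-17-92 list (0.923), miR-106a (0.065), miR-125a-5p (0.07), miR-17 (0.040), miR-19b (0.26), miR-20a (0.10) and miR-222 (0.20). The cause of the other turns was not tested.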

Other observations

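Values without the stem array of donor A and the relation of miR-205 to the miR-200 family were chosen after seeing the data. Without the stem array of donor A, miR-765, miR-583 and miR-483-5p, which were higher in stem cells than in epithelium, were higher than in stroma too. miR-765 was 7.03-fold and miR-583 at least 3.59-fold higher than in stroma, above the negative control limit on 5 and 2 of 6 stromal arrays (log2 differences of 2.81 and 2.38, SE 0.46 and 0.24, limma adjusted p = 0.000285 and 2.34e-06), in 4 of 4 donors each. The rule for named probes required the same sign in every donor. miR-483-5p lay at 2.30 (adjusted p = 0.000415). miR-658 and miR-198 were also higher than in stroma, at 2.26 and 1.74 (adjusted p = 0.00534 and 0.000172).

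Muscle microRNAs varied widely between stromal arrays. miR-206, a microRNA of skeletal muscle, had a log2 intensity of 14.01 for donor B and 12.96 for donor E, and of 10.76, 9.63, 8.91 and 8.82 for donors D, C, A and F. miR-1, abundant in heart and skeletal muscle, reached 12.34 for donor B and 10.81 for donor E. Muscle cells in some stromal samples may account for this as a hypothesis, since miR-206 correlated over the 6 stromal arrays with the mean of miR-1 and the miR-133 probes with r = 0.977 (exact two-sided permutation p = 0.00139, the smallest that 6 arrays allow, adjusted p = 0.00833 over 6 relations) and rho = 1 (exact permutation p = 0.00278, adjusted p = 0.0167), and r was 0.991 without the 2 arrays farthest from the median. Stromal cells that make these microRNAs themselves would give the same relation, and the labels name no sort or gate. miR-206 differed within both batches with stromal arrays, donors A to D in the one and donors E and F in the other. Stem arrays varied as well, with miR-206 and miR-1 at 10.60 and 9.40 for donor E. They lay at 10.53 and 10.69 for donor A, whose stem array carried little microRNA signal, so these normalised values are not read as levels. On the other stem arrays miR-206 lay at 8.64 to 8.91 and miR-1 at 7.92 to 8.16.

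Over the 6 stromal arrays miR-205 also correlated with the mean of the miR-200 family (r = 0.919, exact two-sided permutation p = 0.00972, adjusted p = 0.0292 over 6 relations, and rho = 0.943, p = 0.0167, adjusted p = 0.05), with r = 0.787 without the 2 arrays farthest from the median.

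The array with the conflicting label correlated across human probes with the epithelial arrays at 0.939 to 0.974, with the stem arrays at 0.898 to 0.914 without that of donor A, which stood at 0.336, and with the stromal arrays at 0.805 to 0.907, and probes are not independent replicates. On it miR-141 was at 13.39, miR-205 at 12.58, miR-200c at 12.52, miR-143 at 9.06, miR-199a-5p at 9.0, miR-214 at 8.37 and miR-100 at 9.96 in log2 intensity.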
